A study of Mus musculus with 4 samples.

How the data were processed

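RNA was measured in 4 libraries of cultured mouse cells, female germline stem cells per the labels, called library 01, 02, 21 and 22 after the numbers in their titles. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was selected with oligo(dT) beads, fragmented, primed at random and sequenced as paired-end reads. The labels name no step that keeps the strand, so it is not known whether reads from overlapping genes on opposite strands were told apart. The series design speaks of celastrol-treated and control cells at 12 h in triplicate, but 4 samples are listed and their labels are identical apart from the library numbers. No library was therefore placed in a treated or control group, and no test between groups was run. Every statistic describes these 4 libraries and not the treatment.

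The deposited table holds a raw read count and an FPKM value for each of 55359 Ensembl mouse genes in each library, per the file headers and the values. The count columns hold whole numbers that sum to a different total in each library, so the deposited counts were taken as not normalised. FPKM, fragments per kilobase of exonic gene size scaled to the depth of the library, was computed by the authors, per the file headers. Dividing each count by the exonic size in kilobases and by the FPKM returned the summed count of the library within 0.05% for every gene above 10 FPKM, so the authors' FPKM is scaled to all counts in the table. FastQC, HISAT2 and DESeq2 are named in the submitters' processing notes with no version and no role. The read counter, the genome build and the annotation release are not given in the sources used here. Of 52083 gene identifiers shared with the GENCODE M21 annotation of GRCm38, 1499 had the same start, so the coordinates are printed as deposited, without a build, and none was converted.

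Symbols were taken from the deposited table, in which 1438 genes had none. The 28 gene lists held 470 different symbols, of which 469 were found. Rigi was the symbol without a match, since the table lists that gene as Ddx58, so the interferon-stimulated list leaves out a gene that was measured. Where a symbol had several identifiers, the identifier with the higher median was used. A gene was called detected at 1 FPKM or more. The log2 range of a gene is the highest minus the lowest log2(FPKM + 1) over the 4 libraries. Ranges were computed for genes with a mean of 1 FPKM or more, and the pseudocount makes the range of low genes smaller than their fold difference. For each list with at least 3 such members the median range was set against 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes how far the list varied over these libraries. Lists with fewer such members have no percentile. Pearson r of log2(FPKM + 1) and Spearman rho were computed for the 6 pairs of libraries across genes, which are not independent replicates. The mean Pearson chi-square per gene, over genes with at least 20 counts summed over the pair, compares the counts of a pair with sampling noise, for which it is 1.

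Counts carry exact Poisson 95% intervals, converted to FPKM, and shares of counts carry Wilson 95% intervals. The floor is 3 counts in a library. Intervals and floors cover counting error only, because PCR copies of a molecule are not independent. The range and chi-square calculations were tested on simulated Poisson counts. Of 87 genes changed 3-fold in 1 simulated library, 100% passed a log2 range of 1, against 0% of 84 genes changed 1.5-fold and 1.096% of 11674 unchanged genes. The changed genes had a mean of 100 counts and 5 FPKM or more, and the unchanged genes a mean of 1 FPKM or more. The changed genes therefore check the calculation and do not measure how often changes in low genes are found. The chi-square of unchanged simulated libraries was 0.990. Shared sequence was measured as the percent of 100-base stretches of a gene's GENCODE M21 transcripts found in the transcripts of no other gene. That annotation is not known to be the authors' own.

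The text names genes by a rule fixed, like the lists and the processing alternatives, before the data were examined. It takes up to 3 members of each list with the highest median FPKM and the member with the widest range, all members of the inflammasome and cGAS-STING lists, the 10 genes with the highest medians and the 20 genes with the widest ranges among 7731 genes with a mean of 5 FPKM or more. Some genes that the rule takes are not reported here. Any other gene was chosen after its values were seen, and the text says so. A further 8 cell identity lists (mast cell, macrophage, general blood cell, melanocyte, trophoblast, skeletal muscle, neural and spermatogonia) were written after the values of the fixed lists were seen and before the remaining members were looked up. The alternatives were other detection thresholds and pseudocounts, a rescaling of each library to a common sum of FPKM, median-of-ratios size factors, removal of the 10 highest and the mitochondrial genes followed by the same rescaling, other filters on low values, and leaving out each library in turn. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.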

Results

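Female germline stem cells are cells grown from mouse ovary in a medium with leukemia inhibitory factor, glial cell line-derived neurotrophic factor, basic fibroblast growth factor and epidermal growth factor. The study asked, by its title, how the STING pathway and the inflammasome receptor NLRP3 take part in the pyroptosis caused by celastrol, a plant triterpenoid. Poly(A) RNA of 4 libraries labelled as such cells was sequenced, and the labels do not say which received celastrol. Values are therefore given for each library, always in the order 01, 02, 21 and 22, with no comparison between conditions and no replicate error. The libraries held 12339636, 13039541, 12388380 and 12850347 counts. At 1 FPKM or more, 11913, 11978, 11854 and 11883 genes were detected, of which 11107 were detected in all 4 libraries.

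The genes of the cGAS-STING pathway, which senses DNA in the cytosol, were mostly detected in these libraries. The values of this and the following lists do not show which cells made the RNA. Of 20 list members, 15 were at 1 FPKM or more in every library, and the list median was 7.54, 7.59, 9.2 and 8.89 FPKM. Sting1 (ENSMUSG00000024349, chromosome 18, 35866732 to 35873607 on the minus strand, build not given in the sources used here) was at 7.18, 6.88, 13.8 and 12.1 FPKM. Its log2 range of 0.90 was the widest of the list, and the Poisson 95% intervals of its lowest library, 02 (6.05 to 7.799 FPKM), and its highest, 21 (12.5 to 15.1 FPKM), did not overlap. Cgas, the sensor upstream of STING, was at 7.9, 8.74, 7.49 and 6.62 FPKM. The kinase gene Tbk1 was at 17.2, 14.8, 15.5 and 14.4 FPKM and the transcription factor gene Irf3, with a log2 range of 0.03, at 16.4, 16.4, 16.2 and 16.6 FPKM. Irf7 stood near the detection limit at 1.09, 0.63, 1.48 and 1.15 FPKM, and Zbp1 was under it at 0.73, 0.76, 0.94 and 0.79 FPKM. Ikbke (2.595 FPKM, median of the libraries), Ifi204 (2.59), Rnaseh2b (4.28), Samhd1 (8.19), Stim1 (8.29), Rnaseh2c (11.1), Trim56 (11.7), Rnaseh2a (14.5), Trim32 (17.96), Sec24c (25.6) and Ddx41 (27.1) had log2 ranges of 0.03 to 0.40. Ifnb1, the interferon beta gene induced by this pathway, had 1 count in library 22 and none in the others. Enpp1 and Trex1 had no count in any library, where the floor of 3 counts equals at most 0.0237 FPKM of Enpp1 and 0.212 FPKM of Trex1. Only 8.31% of the 100-base stretches of Trex1 were unique to it, so its value is uncertain. The median range of the list, 0.25, was wider than in 37.1% of random lists.

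The inflammasome and pyroptosis list was transcribed in part. Of 26 members, 15 were at 1 FPKM or more in every library and 11 were under 1 FPKM in every library, with a list median of 2.78, 2.92, 2.64 and 3.09 FPKM. Nlrp3 (ENSMUSG00000032691, chromosome 11, 59432394 to 59457782 on the plus strand, build not given in the sources used here) was at 2.72, 3.63, 4.52 and 4.49 FPKM, from 136, 192, 227 and 234 counts. Its Poisson 95% intervals were 2.28 to 3.21, 3.13 to 4.18, 3.95 to 5.14 and 3.93 to 5.102 FPKM, and its log2 range was 0.57. Casp1, the caspase that inflammasomes activate, had 1, 2, 0 and 0 counts and a Poisson upper bound of at most 0.177 FPKM in any library. Il1b, whose product caspase-1 matures, had a single count, in library 21. Casp4, the caspase of the noncanonical pathway, was at 4.65, 4.96, 5.4 and 5.22 FPKM, and the adaptor gene Pycard at 3.48, 2.83, 2.93 and 3.36 FPKM. Gsdmd, the pore-forming substrate of both caspases, was at 8.66, 7, 5.47 and 6.51 FPKM, and Gsdme at 3.6, 3.53, 3.4 and 3.87 FPKM. The channel gene P2rx7 had the widest range of the list, 0.81, at 6.04, 7.67, 4.16 and 3.94 FPKM. Hmgb1 followed with a range of 0.73 at 45.2, 39.1, 65.3 and 54.6 FPKM, although 81.9% of its stretches were unique to it and near-identical copies can take part of its reads. Il18 was at 1.26, 1.56, 2.35 and 1.89 FPKM, Il1a at 3.28, 4.74, 3.35 and 3.59 FPKM, Aim2 at 3.73, 3.02, 2.31 and 2.82 FPKM and Panx1 at 2.84, 3.13, 4 and 3.68 FPKM. Ninj1, whose product ruptures the membrane of dying cells, was at 52.3, 52.2, 49.4 and 47.6 FPKM, with Nek7 at 37.2, 38.4, 39.9 and 43.4 FPKM and Txnip at 22.3, 22.6, 25.6 and 25.1 FPKM. Among the Naip genes, which are close paralogs whose reads can be misassigned, Naip2 had a median of 6.16 FPKM, Naip5 of 0.765 and Naip1 of 0.015. Nlrc4, Nlrp1b, Nlrp6 and Gsdma had at most 0.12 FPKM in any library, and Gsdmc, Nlrp1a and Mefv had no count. The median range of the list, 0.38, was wider than in 95.03% of random lists.

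**Figure D1:**
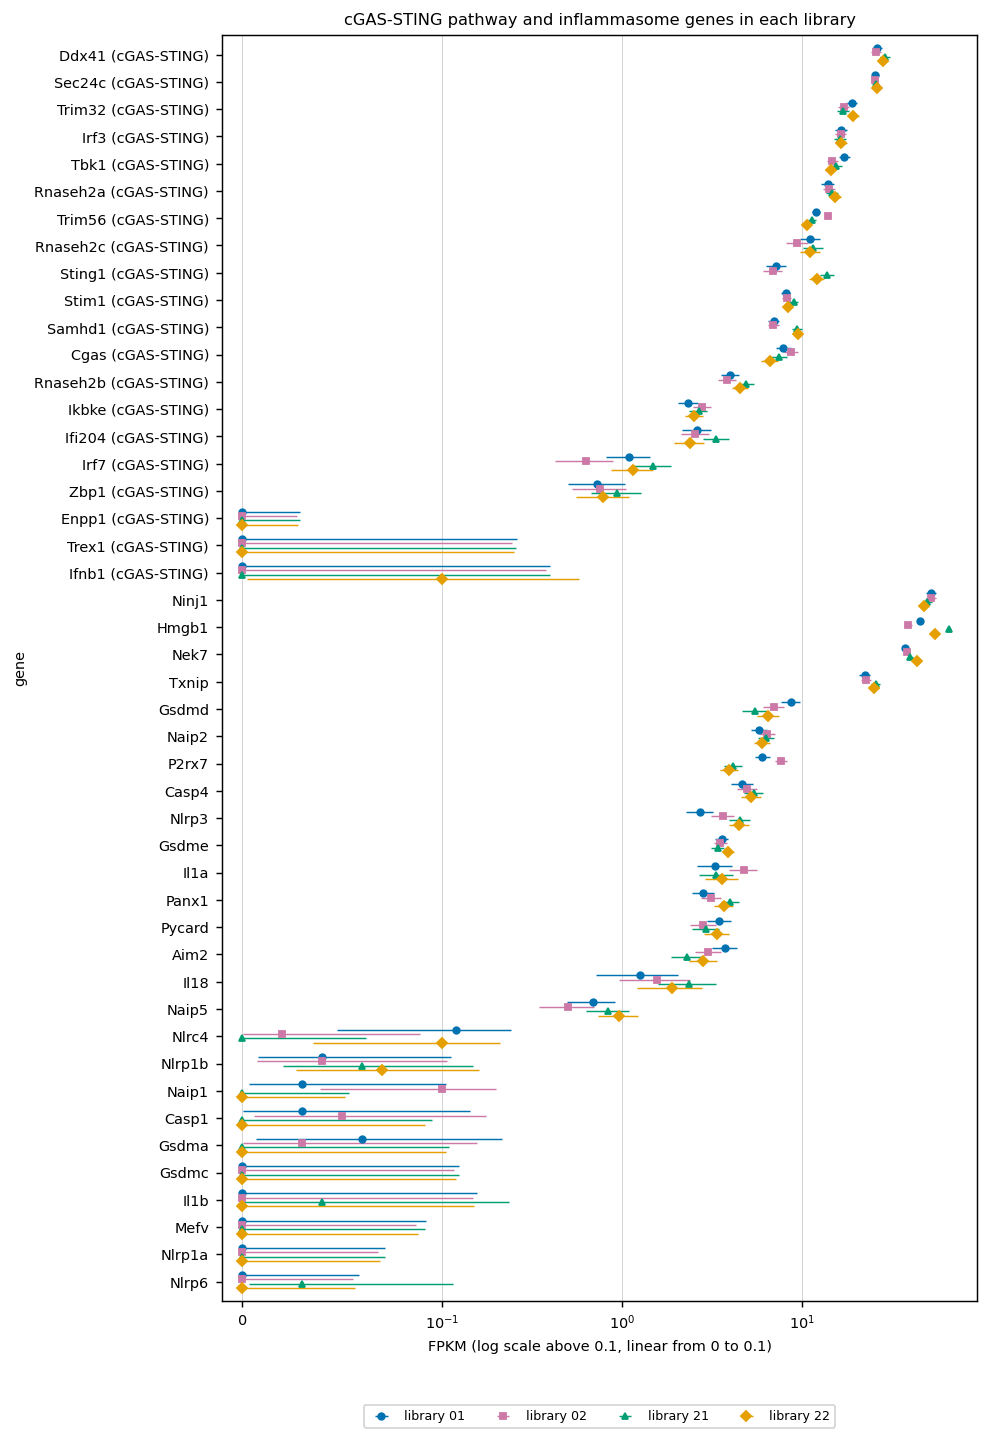
FPKM of each member of the cGAS-STING and inflammasome lists in each of the 4 libraries, on an axis that is logarithmic above 0.1 and linear under it, with exact Poisson 95% intervals as bars. Sting1 lay between 6.88 and 13.8 FPKM and Nlrp3 between 2.72 and 4.52 FPKM, while Casp1 and Il1b lay near 0.

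Most germ cell markers were under the detection limit in these libraries. Of the 30 female germline stem and germ cell markers, 20 were under 1 FPKM in every library, 9 were at 1 FPKM or more in every library, and 8 had no count at all. The list median was 0.065, 0.07, 0.07 and 0.065 FPKM, and the median range of the detected members, 0.27, was wider than in 59.2% of random lists. Ddx4, the germ cell RNA helicase, had 0, 2, 0 and 0 counts, and Dazl, a germ cell RNA-binding protein gene, had 0, 4, 0 and 0, where 3 counts equal at most 0.0807 FPKM of Ddx4 and 0.0636 FPKM of Dazl (both were chosen after their values were seen). The markers with the highest medians were Ifitm3 at 273, 269, 278 and 272 FPKM, the receptor gene Kit at 58.9, 64.6, 101 and 100.2 FPKM and Cd9 at 26.1, 25.6, 21.7 and 21.4 FPKM, genes that many cell types outside the germline also use. Kit had the widest range of the list, 0.76. The detected members also included Rhox5 at 6.85, 7.43, 5.18 and 5.05 FPKM, Tex14 at 4.83, 5.28, 5.07 and 5.12 FPKM and Piwil2 at 2.54, 2.42, 1.44 and 1.88 FPKM, genes known from the germline that were named after their values were seen. Of 14 naive pluripotency genes, 4 were at 1 FPKM or more in every library and the list median was 0.055, 0, 0 and 0.02 FPKM. Myc led that list at 113, 119, 47.1 and 46.7 FPKM with a log2 range of 1.33, followed by Klf5 at 5.06, 4.85, 4.56 and 4.8 FPKM and Tbx3 at 3.98, 3.06, 2.12 and 2.43 FPKM, and the median range of 0.41 was wider than in 77.7% of random lists. All 20 oocyte and meiosis genes were under 1 FPKM in every library, 8 of them without a count, and the highest, Sycp1, Rec8 and Gdf9, had medians of 0.515, 0.405 and 0.27 FPKM. Receptors of the growth factors in the medium had a list median of 0.535, 0.515, 0.49 and 0.49 FPKM, with 4 of 10 members at 1 FPKM or more in every library. These were led by Fgfr1 at 16.9, 15.7, 11.5 and 11.1 FPKM, Sdc4 at 13.1, 12.98, 11.6 and 14.3 FPKM and Il6st at 6.73, 7.84, 7.9 and 7.76 FPKM, with a median range of 0.24, wider than in 31.6% of random lists. Gfra1 and Ret, which encode the receptor of glial cell line-derived neurotrophic factor, were at 0.09, 0.1, 0.07 and 0.06 FPKM and 0, 0.06, 0.05 and 0.12 FPKM, and were named after their values were seen.

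**Figure D2:**
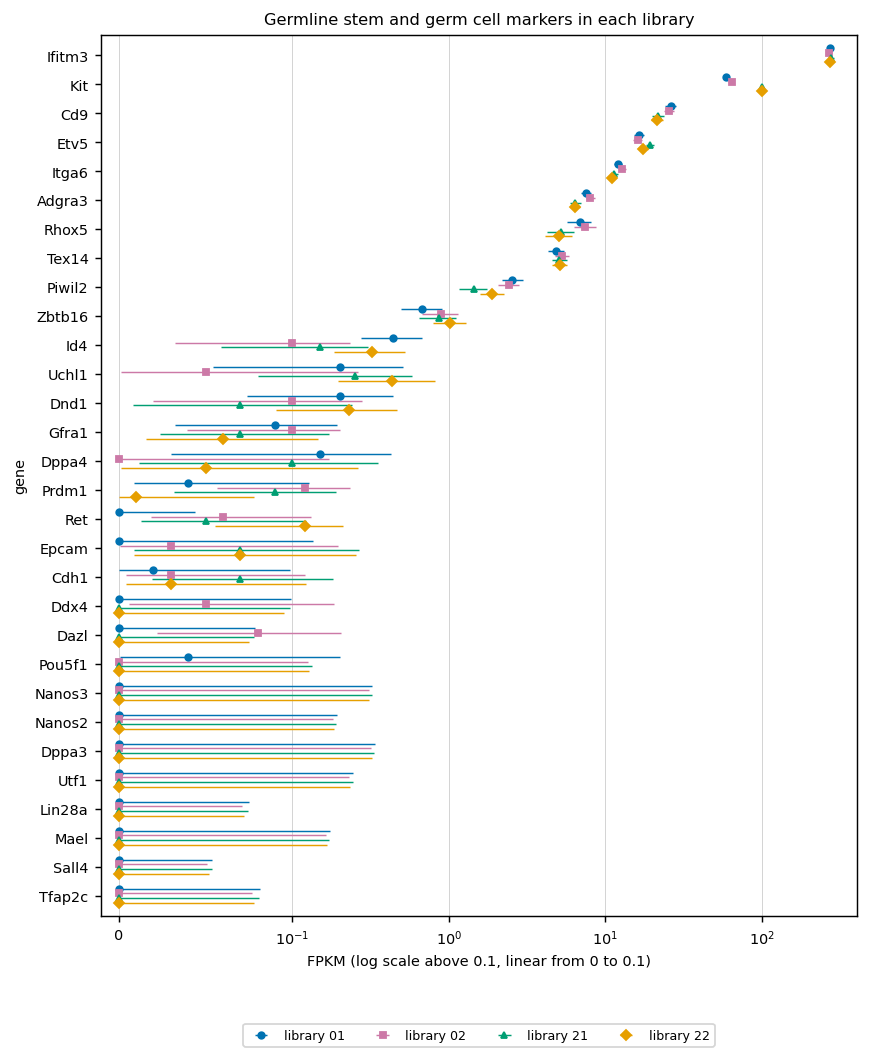
FPKM of the 30 female germline stem and germ cell markers in each of the 4 libraries, on an axis that is logarithmic above 0.1 and linear under it, with exact Poisson 95% intervals as bars. Ifitm3 and Kit lay highest, and 20 markers lay under 1 FPKM in every library.

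The list that varied most over the libraries was that of the NRF2 oxidative stress response, which holds genes of antioxidant and iron-storage proteins among others. All 24 members were at 1 FPKM or more in every library, the list median was 77.2, 74, 41.3 and 45.4 FPKM, and the median range of 0.67 exceeded that of all 10000 random lists, whose median was 0.23. Nqo1, a quinone reductase gene, was at 143, 139.6, 34.6 and 31.1 FPKM, a log2 range of 2.17. The peroxiredoxin gene Prdx1 was at 827, 808, 229.9 and 235 FPKM, a range of 1.84. The ferritin genes Ftl1 and Fth1 were at 3324, 3078, 1825 and 1815 FPKM and 1659.6, 1535, 958 and 961 FPKM. Of the 24 members, 3 had a log2 range over 1, the third being Gclm (named after its values were seen) at 47.1, 44.9, 22.3 and 21.9 FPKM. Among heat shock genes 19 of 20 members were detected in every library, with a list median of 34.6, 36.5, 39.5 and 39.8 FPKM and a median range of 0.27, wider than in 82.2% of random lists. Hsp90ab1 was at 2444, 2386, 2038 and 2074 FPKM, Hsp90aa1 at 960.2, 975, 548 and 583 FPKM and Hspd1 at 752, 725, 657 and 680.1 FPKM, and the small heat shock gene Cryab had the widest range, 1.83, at 38.8, 42.8, 11.3 and 12.7 FPKM. The unfolded protein and integrated stress response list, with 22 of 23 members detected in every library, had a median of 84.96, 84.5, 98.4 and 95.8 FPKM and a median range of 0.24, wider than in 72.3% of random lists. The endoplasmic reticulum chaperone genes Calr, Hspa5 and Hsp90b1 led it at 471, 459.5, 664 and 643 FPKM, 407, 397, 457 and 469 FPKM and 363, 356, 400.1 and 421 FPKM, and the stress kinase gene Eif2ak3 had its widest range, 0.81, at 5.34, 6.29, 10.1 and 10.1 FPKM. Of 6 genes of metallothioneins and metal transport, 5 were detected in every library, with a list median of 12.4, 11.4, 10.2 and 9.78 FPKM and a median range of 0.45, wider than in 97.7% of random lists. Mt2 was at 284, 314, 164 and 178 FPKM, Mt1 at 157, 139.7, 123 and 114 FPKM and Slc39a10 at 13.7, 12.96, 12.7 and 12.3 FPKM. Autophagy and lysosome genes, all 18 detected in every library, had a list median of 17.3, 16.1, 18.5 and 18.2 FPKM and a median range of 0.28, wider than in 80.1% of random lists. The cargo receptor gene Sqstm1 was at 494, 488, 377 and 372 FPKM, the cathepsin genes Ctsd and Ctsl at 309.6, 297, 169 and 165 FPKM and 192, 188, 99.9 and 103 FPKM, and Lamp1 at 192, 185, 177 and 180.2 FPKM.

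**Figure D3:**
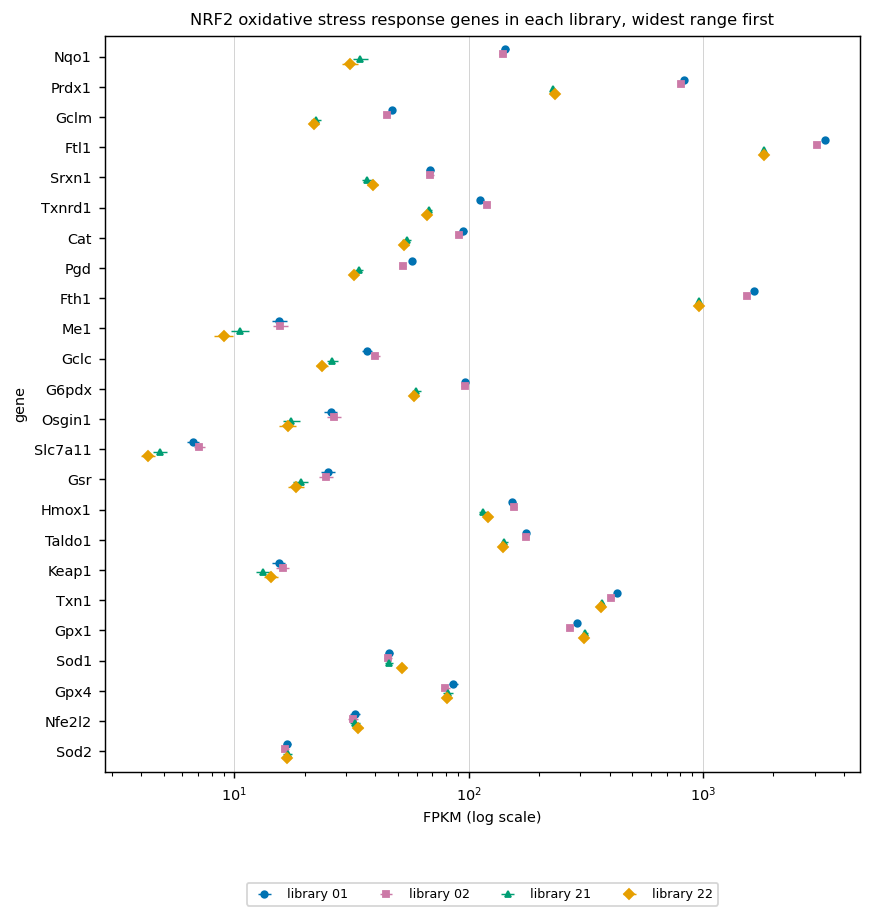
FPKM of the 24 NRF2 oxidative stress response genes in each of the 4 libraries on a logarithmic axis, sorted by log2 range, with exact Poisson 95% intervals as bars. Nqo1, at the top, spans 31.1 to 143 FPKM, and Sod2, named for its place at the bottom, stays near 17 FPKM in all 4 libraries.

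Inflammatory and death-related genes varied to different degrees. NF-kB and inflammatory genes, 18 of 20 detected in every library, had a list median of 13.4, 13.2, 17.2 and 16.6 FPKM and a median range of 0.43, wider than in 99.9% of random lists. Nfkbia, which encodes the inhibitor of NF-kB, was at 19.6, 19.6, 44.5 and 44.8 FPKM, a log2 range of 1.15. The cyclooxygenase gene Ptgs2 was at 87.3, 93.7, 84.3 and 94.1 FPKM and the chemokine gene Ccl2 at 35.9, 32.7, 46.5 and 46.5 FPKM. Interferon-stimulated genes had low list medians. Of 24 found, 10 were detected in every library, and the list median was 0.9, 1.2, 1.8 and 2.06 FPKM with a median range of 0.37, wider than in 79.95% of random lists. Ifit1 was at 0.46, 0.52, 2.13 and 2.11 FPKM from 15, 18, 70 and 72 counts, Ccl5 at 4.56, 4.95, 10.6 and 9.73 FPKM, Isg15 at 18.1, 13.2, 24.9 and 23.02 FPKM and Bst2 at 88.2, 93.8, 72.1 and 73.6 FPKM. Immediate early genes had a list median of 13.8, 11.97, 8.62 and 8.69 FPKM, with 16 of 17 detected in every library and a median range of 0.39, wider than in 99.0% of random lists. Ier3 was at 184, 182, 177 and 163 FPKM, Jund at 147, 134, 121 and 122 FPKM, Klf6 at 43.8, 44.3, 40.9 and 40.9 FPKM and Egr1, with the widest range of 0.93, at 13.8, 11.97, 7.47 and 6.73 FPKM. The p53 and DNA damage list, 18 of 20 detected in every library, had a median of 19.5, 19.3, 19.9 and 20.3 FPKM and a median range of 0.42, wider than in 99.8% of random lists. Its leading members were Bax at 102, 102, 87.7 and 84.6 FPKM, Cdkn1a at 98.3, 90.6, 74.5 and 72.5 FPKM and Ccng1 at 48.6, 52.7, 64.5 and 68.2 FPKM, and Gadd45g had the widest range, 0.88, at 40.8, 38.6, 23.8 and 21.8 FPKM. Apoptosis machinery genes varied less, with a list median of 8.12, 8.7, 8.29 and 9.48 FPKM, 18 of 20 detected in every library, and a median range of 0.23, wider than in 23.6% of random lists. Mcl1 was at 55.98, 54.01, 49.95 and 51.1 FPKM and Bak1 at 54.3, 52.7, 51.1 and 47.7 FPKM. The survival gene Bcl2 had the widest range of that list, 0.95, at 29.9, 32.8, 16.4 and 17.2 FPKM.

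Of all lists with a median range, those of housekeeping and of hypoxia and glycolysis genes varied least. All 27 cell cycle genes were detected in every library, with a list median of 33.2, 34.99, 40.3 and 41.2 FPKM and a median range of 0.26, wider than in 78.2% of random lists. The replication genes Mcm3, Pcna and Mcm6 were at 110.3, 102, 126 and 135 FPKM, 104, 102, 114 and 121 FPKM and 99.8, 94.5, 104 and 101 FPKM, and Mki67 was at 26.8, 34.99, 34.5 and 40.1 FPKM. The hypoxia and glycolysis list, all 20 detected in every library, had a median of 55.3, 53.8, 56.2 and 56.5 FPKM and a median range of 0.17, wider than in 8.72% of random lists. Aldoa was at 842, 808, 755 and 764 FPKM, Ldha at 575, 544, 637 and 644 FPKM, Pkm at 621, 618, 575 and 568 FPKM and the glucose transporter gene Slc2a1 at 142, 129, 102 and 108 FPKM. Cholesterol synthesis genes, all 15 detected in every library, had a list median of 11.4, 10.7, 14 and 14.2 FPKM and a median range of 0.33, wider than in 91.7% of random lists. Cyp51 was at 23.2, 22.2, 27.1 and 28.1 FPKM, Srebf2 at 17.97, 19.1, 21.3 and 19.2 FPKM and Idi1 at 1.46, 2.36, 2.79 and 3.13 FPKM. The 12 housekeeping genes had a list median of 122, 118, 123 and 127 FPKM and a median range of 0.14, wider than in 1.93% of random lists. Eef1a1 was at 5145, 4974, 5361 and 5363 FPKM, Rplp0 at 1486, 1492, 1485 and 1483 FPKM, Actb at 969, 946, 926 and 886 FPKM and Sdha at 71.02, 70.7, 87.7 and 83.1 FPKM. Of 13 mitochondrially encoded mRNAs, 12 were detected in every library, with a list median of 635, 595, 594 and 659 FPKM and a median range of 0.38, wider than in 97.8% of random lists. The exception, mt-Nd3, had 14, 6, 8 and 4 counts and a log2 range of 1.17. The mRNAs mt-Co1, mt-Nd1 and mt-Cytb were at 5957, 5941, 6091 and 6231 FPKM, 2737, 2659, 2809.7 and 2923 FPKM and 2292, 2292, 2365 and 2498 FPKM. Mitochondrial mRNAs took 1.91%, 1.90%, 1.91% and 2.00% of counts, with Wilson 95% intervals within 1.89% to 2.01% over the libraries, and 4.41%, 4.44%, 4.41% and 4.67% of summed FPKM. These are shares of the deposited values, in which mt-Co2, mt-Atp6 and mt-Co3 (named after their values were seen), each with under 1% of its stretches unique to it, had medians of 31.0, 6.77 and 8.64 FPKM, so the intervals do not bound the share of mitochondrial RNA in the cells.

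Markers of other cell types were present for some lineages and near 0 for others. Of 20 fibroblast or feeder cell markers, 17 were detected in every library, with a list median of 9.91, 10.2, 11.2 and 9.95 FPKM and a median range of 0.23, wider than in 22.1% of random lists. Vim was at 341, 335, 296 and 306 FPKM, S100a4 at 143, 131, 135 and 136 FPKM, Fn1 at 119, 139.9, 125 and 123 FPKM and Twist1 at 3.14, 3.58, 5.6 and 3.01 FPKM. The macrophage and leukocyte list had a median of 1.74, 1.52, 1.59 and 1.52 FPKM, with 6 of 12 members detected in every library and 5 under 1 FPKM in every library. Its highest members were Adgre1, the gene of the surface antigen F4/80, at 218, 220.5, 97.7 and 96.2 FPKM, the Fc receptor chain gene Fcer1g at 43.7, 37.3, 36.6 and 39.6 FPKM and Cd68 at 25.3, 25.5, 11.7 and 13.2 FPKM. The median range of the detected members, 0.41, was wider than in 96.4% of random lists. Of 13 granulosa cell markers, 9 were under 1 FPKM in every library and 2 were detected in every library, with a list median of at most 0.04 FPKM in any library. The highest were Inhba at 3.99, 5.34, 5.05 and 6.25 FPKM, Gata4 at 2.16, 1.98, 1.47 and 1.75 FPKM and Hsd17b1 at 1.39, 1.32, 0.9 and 0.81 FPKM, Fst had the widest range, 0.57, and the median range of 0.47 was wider than in 68.4% of random lists. Of 8 theca and luteal markers, 2 were detected in every library, with a list median of 0.275, 0.255, 0.16 and 0.31 FPKM. These were Cyp11a1, the first enzyme of steroid synthesis, at 91.3, 90.5, 73.9 and 74.9 FPKM and Ptch1 at 3.95, 4.23, 3.52 and 3.4 FPKM, while Star was at 0.97, 0.82, 0.57 and 0.62 FPKM. Cyp11a1 also stands in the mast cell list, so its level does not point to theca and luteal cells alone. The 7 endothelial markers included 1 detected in every library, Egfl7, at 4.78, 5.48, 8.18 and 7.26 FPKM, and 6 under 1 FPKM in every library, with Cdh5 and Pecam1 at medians of 0.255 and 0.13 FPKM. Of 9 surface epithelium markers, 8 were under 1 FPKM in every library, among them Krt8 and Lhx9 with medians of 0.08 and 0.065 FPKM, and the exception was Msln at 51.8, 50.3, 48.8 and 47.3 FPKM. All 6 sex chromosome genes were under 1 FPKM in every library. Xist, the transcript that silences an X chromosome in female cells, had 2, 2, 4 and 5 counts, and the other 5, Tsix and the Y-linked Ddx3y among them, had none.

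The 10 highest genes of each library took 9.95%, 9.96%, 9.62% and 9.32% of summed FPKM, and the 10 highest by counts took 6.37%, 6.26%, 5.81% and 5.57% of counts. The 10 genes with the highest median FPKM were mt-Co1, Eef1a1, Rn18s, Rplp1, mt-Nd1, Ftl1, mt-Cytb, Hsp90ab1, Rps15 and Eef2. Rplp1, Rps15 and Eef2, which encode parts of the translation machinery, were at 3153, 2995, 3203 and 3123 FPKM, 1961, 1872, 2143 and 2163 FPKM and 1687, 1678, 1837 and 1822 FPKM. The 18S ribosomal RNA gene Rn18s, a transcript without a poly(A) tail, was at 4763, 4908, 4657 and 3115 FPKM, lowest in library 22. Pearson r of pairs of libraries across 11874 genes was 0.979 to 0.990 and Spearman rho 0.977 to 0.989. The mean chi-square per gene was 3.03 to 19.6 over the 6 pairs against 1 for sampling noise, so no pair agreed within sampling noise. Single genes with high counts can raise this mean, such as Rn18s with 106677 counts in library 21 and 74018 in library 22. It is therefore not the scatter of a typical gene.

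Of 11874 genes with a mean of 1 FPKM or more, 429 (3.61%) had a log2 range over 1, that is, a difference of more than 2-fold between their highest and lowest library. In simulated unchanged libraries, counting noise alone put 1.096% of genes over that limit. That share leaves out the further scatter between real libraries, whose chi-square was at least 3.03, so the excess over it is not a count of true differences. Among 9892 genes that also had a mean of 100 counts or more, a limit chosen after the data were seen, 72 passed. The median range was 0.27 and the 95th percentile 0.86. Among the 20 genes with the widest ranges, 12 had a mean over 100 counts. Apart from Nqo1, Prdx1 and Cryab, they included Gsta4, a glutathione transferase gene, at 21.2, 20.6, 3.7 and 6.95 FPKM, and the transferrin receptor gene Tfrc at 451, 453, 118 and 124 FPKM, with log2 ranges of 2.24 and 1.93. The protease inhibitor gene Serpinb2 was at 10.6, 12.3, 35.4 and 38.4 FPKM, a range of 1.77, and Tmem273 at 11.7, 8.51, 4.03 and 2.86 FPKM. Gm21399 and Gm35037 were at 26.6, 28, 4.6 and 6 FPKM and 24.3, 25.3, 5.74 and 7.23 FPKM. The pseudogene Rps26-ps1 had the widest range, 2.41, at 10.7, 22.6, 15.1 and 60.8 FPKM, and with Rps27rt at 613, 305, 154 and 176 FPKM and Gm12751 at 66.6, 115, 157 and 47.8 FPKM it is among the shorter genes of the table, at 449, 374 and 381 exonic bases. Reads of Rps26-ps1 and Rps27rt can be shared with the ribosomal protein genes they resemble, so their values are uncertain. The remaining 8, Mir3060, Gm23201, Snord89, Mir1898, Trgj1, Snord49a and the genes ENSMUSG00002075524 and ENSMUSG00002076924 without a symbol, were under 300 bases long with at most 24 counts in any library.

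**Figure D4:**
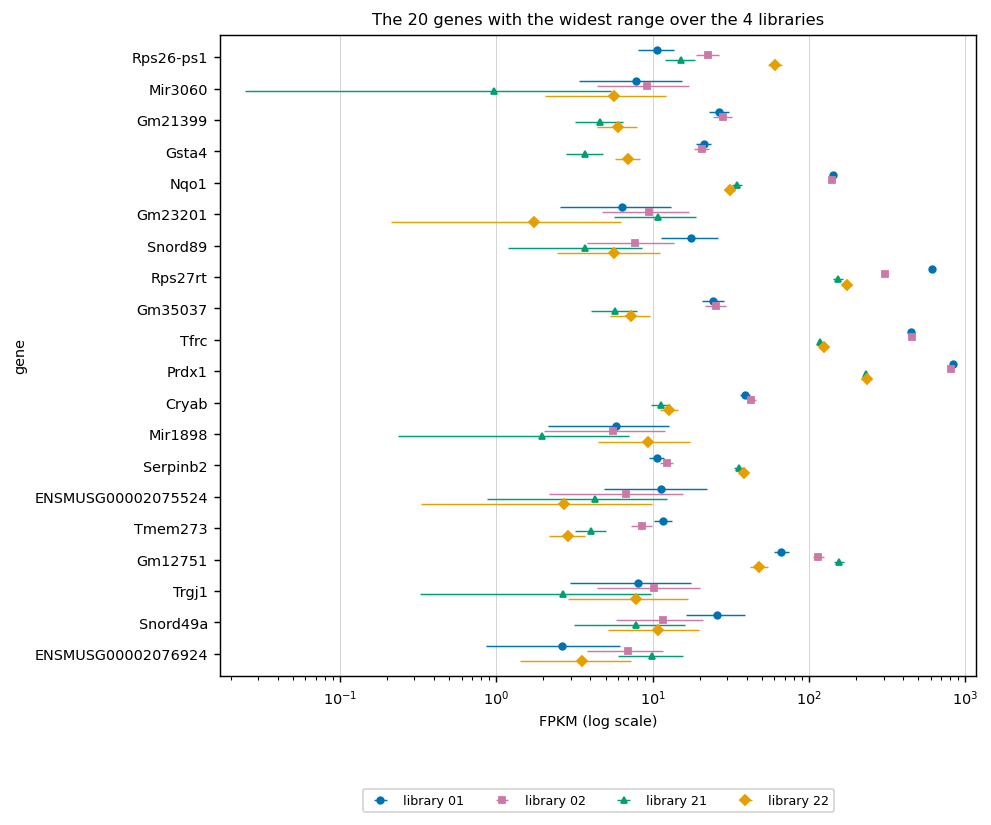
FPKM of the 20 genes with the widest log2 range among 7731 genes with a mean of 5 FPKM or more, in each of the 4 libraries on a logarithmic axis, with exact Poisson 95% intervals as bars. The intervals of the 8 genes under 300 bases span several-fold, while those of Nqo1, Tfrc and Prdx1 are narrower than the distance between their highest and lowest library.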

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

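The minimum of 100 counts and the shares of counts were added after the data were seen, and the other alternatives were planned. The count of genes with a log2 range over 1, 429 as reported, depended on the scale and the filter. It was 826 with a pseudocount of 0.1, 65 with a pseudocount of 5, 686 after each library was rescaled to a common sum, 708 after the 10 highest and the mitochondrial genes were removed and the rest rescaled in the same way, 898 with no filter, 93 among genes with a mean of 5 FPKM or more and 72 among genes with a mean of 100 counts or more. The rescaled values are about 3 times the FPKM, so the pseudocount weighs less on them, by construction. Leaving out each library in turn gave 314 to 332 genes, fewer because 3 libraries span less than 4. A threshold of 5 FPKM gave 7741, 7799, 7679 and 7675 detected genes in libraries 01, 02, 21 and 22, fewer by construction. The lowest r of the pairs was 0.961 with a pseudocount of 0.1 and 0.991 with no filter, which adds genes near 0 in every library, and the highest r was 0.9754 with a pseudocount of 0.1. The cause of the changes in r was not tested further. The 50 highest genes took 23.2%, 23.1%, 22.6% and 22.3% of summed FPKM. Of counts, the 10 highest took 6.37%, 6.26%, 5.81% and 5.57%. FPKM divides each count by the exonic size of the gene, so shares of counts and of summed FPKM differ by construction.

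Of 28 gene lists, 18 had a median of 1 FPKM or more in every library, against 20 after rescaling to a common sum, 18 with size factors, 19 of 27 after the highest genes were removed and the rest rescaled, which leaves no mitochondrial list. With members of a mean under 1 FPKM left out it was 26 of 26 lists that keep a member, which is nearly fixed by construction. Size factors moved none of the 112 list medians beyond the 95% range of 200 Poisson redraws of the counts. Rescaling raised 100 of them beyond it, removing the highest genes and rescaling the rest raised 96 of 108, a pseudocount of 5 moved 108 and a pseudocount of 0.1 moved 81, the former upward and the latter downward, and leaving out members with a mean under 1 FPKM raised 74 of 104. Among 134 named genes, size factors took none across a log2 range of 1. Rescaling took Bcl2 over it, a pseudocount of 0.1 took Irf7, Egr1 and Idi1 over it, and a pseudocount of 5 took 6 under it, Ccl5, Ifit1, Cd68, mt-Nd3 and Trgj1 among them. Depth limits what can be said of differences between libraries for genes with few counts, such as Casp1, Il1b, Ifnb1 and Xist, whose Poisson upper bounds all lay under 1 FPKM.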

Other observations

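The tests of macrophage RNA, blood lineage RNA and all tests on the distance between libraries were chosen after the results they bear on were seen, and the genes named here outside the fixed rule were chosen after their values were seen.

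Genes of blood cells were also detected. All 16 members of a general blood cell list were at 1 FPKM or more in every library, from Lmo2 at 5.69, 7.51, 4.4 and 4.78 FPKM and Gfi1b at 6.64, 5.03, 10.8 and 9.1 FPKM up to the leukocyte genes Coro1a at 114, 109, 131 and 133 FPKM, Laptm5 at 94.97, 99.3, 102 and 105 FPKM and Lcp1 at 103, 105, 98.5 and 98.3 FPKM, with the transcription factor genes Ikzf1 at 36.7, 37.2, 43.8 and 43.05 FPKM and Spi1 at 21.5, 21.9, 22.2 and 22.5 FPKM between them, in libraries 01, 02, 21 and 22. Of 15 mast cell genes, 8 were at 1 FPKM or more in every library, with the carboxypeptidase gene Cpa3 at 333, 325, 229 and 247 FPKM, Gata2 at 173, 165, 131 and 135 FPKM and Il1rl1 at 59.2, 63.9, 50.3 and 53.2 FPKM. The count was 6 of 16 for macrophage genes, 2 of 10 for melanocyte genes (Kit and Mitf), 1 of 12 for trophoblast genes, 1 of 10 for skeletal muscle genes (Des), 1 of 10 for neural genes (Tubb3) and 0 of 12 for spermatogonial genes. The trophoblast gene was Prl2c2, a member of a family of close paralogs, at 322, 318, 286 and 289 FPKM. Of these members, 3 mast cell, 11 macrophage, 11 spermatogonial and 1 each of the general blood cell, melanocyte, trophoblast and neural genes also stand in the fixed lists.

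The blood cell genes Adgre1, Ptprc, Kit and Fcer1g were at 10 FPKM or more in every library, where the labels name ovarian germline stem cells and no sort. Csf1r (0.15 FPKM at most), C1qa, C1qb, C1qc (no count) and Lyz2 (1.23 FPKM at most) are abundant macrophage transcripts. The highest of them reached 1.28% of the lowest Adgre1 value, which argues only against macrophages that make these transcripts abundantly. These transcripts were picked after list values had been seen. Itgam, Aif1, Mrc1 and Cx3cr1 of the macrophage list were also low, at most 0.02, 0.37, 0.15 and 0.16 FPKM in any library. Cd68, Fcgr1, Tyrobp and Cd14 were detected, so macrophages as the source are not excluded. The 28.6% of other list members at 1 FPKM or more decide nothing by themselves. RNA from cells of a blood lineage is a candidate source, since 100% of the other general blood cell genes reached 1 FPKM in every library. Such a share does not show that blood cells were the only source, since 17 of 20 fibroblast or feeder cell markers also reached 1 FPKM in every library. Those markers do not argue against blood cell RNA, since RNA of both kinds can be present. RNA from mast cells stays open at 46.2% of the other mast cell genes, because Cpa3 and Gata2 were high while Fcer1a, Tpsb2 and Mcpt4 had no count. No biological explanation from the study design was tested, and how many of these genes female germline stem cells themselves transcribe is not known from these data.

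Most germ cell markers lay near 0, with 20 of 30 under 1 FPKM and 9, Rhox5, Tex14 and Piwil2 among them, at 1 FPKM or more in every library. Loss of reads to identical stretches in other annotated transcripts is argued against for these 20 genes as a set. A median of 100% of their 100-base stretches were found in no other gene, and 18 had 90% or more. Nanos2 had 54.4% and Dppa4 had 86.02%. Gapdh and Ppia, at 79.1% and 86.6%, had medians of only 6.69 and 2.915 FPKM, so partial sharing is not excluded for single genes. Copies outside annotated transcripts, and copies without an identical 100-base stretch, were not searched. Loss of reads to such copies stays open. For scale, mt-Co2, with 0.513% unique stretches, had a median of 31.0 FPKM against 2773 FPKM for mt-Nd1 with 100%, but reads lost to copies were not measured. Too few reads is argued against as well, since 3 counts in the shallowest library equal 0.0907 FPKM for the median marker and at most 0.273 FPKM. Xist was near 0 as well, with 2, 2, 4 and 5 counts in libraries 01, 02, 21 and 22, although the labels name female cells. The Y-linked Ddx3y had no count, and the cause of the low Xist was not tested. The identity of the cultured cells and a mix-up of cultures stay open, and no biological explanation from the study design was tested.

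The libraries fell into pairs, 01 with 02 and 21 with 22. The mean chi-square per gene was 3.21 between 01 and 02 and 3.03 between 21 and 22, but 18.2 between 01 and 21, 19.2 between 01 and 22, 18.6 between 02 and 21 and 19.6 between 02 and 22. Of the 72 genes with a mean of 100 counts or more and a log2 range over 1, 69 had both 01 and 02 above or both below 21 and 22, including Nqo1, Prdx1, Tfrc, Myc and the blood cell genes Adgre1, Cd68 and Fcgr1 (the last at 20.9, 21, 9.7 and 8.96 FPKM in libraries 01, 02, 21 and 22), with 1 gene parted as 01 and 21 against the others and 2 as 01 and 22. The median of the NRF2 list, 77.2, 74, 41.3 and 45.4 FPKM in the same order, was parted in the same way. Of all 429 genes, 223 followed 01 and 02, 108 followed 01 and 21 and 94 followed 01 and 22, where libraries without pairs would give the 3 ways about equal numbers.

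The pairs did not follow depth. Total counts differed by at most 1.06-fold, between 01 and 02. The chi-square of 01 and 21, the pair closest in total counts, was 5.66 times that of 01 and 02. The chi-square already allows for the totals, and both values had been seen, so this does not test depth as the cause. A few genes taking most of the counts is argued against as the cause of these pairs. Without the 50 highest and the mitochondrial genes, the lowest chi-square across the pairs was still 5.24 times the highest inside them. Bias by GC content or gene length is argued against by a ratio of 6.86 after correction in bins of both, against 5.90 for the same genes uncorrected. Celastrol, separate cultures and a batch stay open and were not tested, because no label assigns a library to any of them.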
